A study of Mus musculus with 4 samples.

How the data were processed

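The series measured RNA bound to IGF2BP2 in mouse bone-marrow-derived macrophages (BMDMs, macrophages grown from bone marrow cells) by RNA immunoprecipitation and sequencing, with input libraries beside the immunoprecipitates. It has 4 samples: 2 IGF2BP2 immunoprecipitation libraries and 2 input libraries. Each immunoprecipitation library came with 1 peak list, called separately for that library; the 2 input libraries were not analysed here. Groups and replicate numbers were taken from the sample titles, which do not say whether the replicates came from separate cultures or animals. The labels disagree on the antibody: the sample characteristics name an antibody against IGF2BP2, and the protocol names a monoclonal antibody against the Flag tag.

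Per the submitters' processing notes, bcl2fastq and TopHat2 were used and the genome build was GRCm38. The peak caller, its threshold and any use of the input libraries in calling are not given in the sources used here. Per the file headers and the values, the authors deposited for each peak a whole, unnormalized tag count, with a lowest value of 3. The authors also deposited a maximum height, a coverage signal that gives the largest number of tags stacked at 1 position and never exceeded the tag count. They further gave a length, a summit, the shares of the peak in each transcript region and a gene identifier. Coordinates were 1-based with both ends included. The files held no expression value, input value, fold enrichment or p-value. The depth of the libraries is therefore unknown, and the tags in peaks (189393 in replicate 1 and 324456 in replicate 2) are not a library size. A gene could have a peak because it was bound or because it was abundant, and these values do not separate the possibilities. Peaks of 3 to 5 tags made up 32.5% and 24.3% of the lists.

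Each peak was given the region that covered most of it in the authors' annotation, and the authors' gene identifier without its version. Of the peaks with an identifier, 99.7% in replicate 1 and 99.8% in replicate 2 matched GENCODE release 21 for mouse on GRCm38, which was used for gene spans, transcripts and sequences. Peaks marked antisense or intergenic were given no gene in the gene comparisons. Peaks were shared when they overlapped by at least 1 bp on the same strand. The overlap was computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and bedtools 2.31.1 gave the same counts, 5404 and 5329. It was compared with 1000 random placements of the same peaks (one-sided empirical p). Each peak was placed within the span of the gene the authors named for it, antisense peaks included, or on its chromosome where none was named.

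Gene overlap was tested with a one-sided Fisher's exact test against all 55536 annotated genes. Peak strength was compared over shared pairs with Pearson's r of log2 tags and Spearman's rho. Region shares have exact binomial 95% intervals, and a two-sided Fisher's exact test with Benjamini-Hochberg adjustment compared the libraries. For 18 gene lists, members with a peak in both replicates were compared with all other protein-coding genes by a two-sided Fisher's exact test (scipy 1.17.1), with Benjamini-Hochberg adjustment over the lists (statsmodels 0.14.6). Peaks, tags and genes are not independent replicates: these tests and intervals compare these libraries and cover counting error only, without molecular identifiers to remove PCR copies.

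The sequence motifs DRACH and GGAC, consensus forms of the m6A site, were sought in peaks lying within 1 exon of a representative transcript. Control windows of equal length came from the same region of the same mRNA, in 10 draws, of which the first entered a two-sided Fisher's exact test. That test ignored the matching of each window to its peak. Windows could overlap the peak itself or other peaks of the gene, which draws odds ratios towards 1. The test had been planned on a genome sequence, which was not used here, so intronic peaks were not searched. Another motif, TGGAC, was tried after seeing the data.

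The gene lists, the rule for named genes, and the tests and alternatives not named below as chosen after seeing the data were fixed before the data were examined. The name pattern for histone genes was narrowed afterwards, because it also took major histocompatibility genes, before that list's values were seen. The rule named Tsc1, Pparg and Igf2bp2; the 20 genes highest by the mean rank of their strongest peak, among genes with a shared peak; and up to 4 members per list, ranked alike, with a peak in both replicates. Other genes in the text are members of these lists or were chosen after their values were seen. Symbols unmatched among protein-coding genes were left out, and Aldoa matched 2 identifiers.

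Alternatives chosen beforehand were overlap of at least 50% of both peaks (100 placements), strand ignored, the stronger 50% of each list, equal numbers of the strongest peaks, another background, maximum height, each replicate alone, gene length as a covariate in a logistic regression, the reference annotation at the peak midpoint, peaks extended by 50 nt, and shuffled sequences keeping dinucleotides. Chosen after seeing the data were placement within the same region of the gene (200 placements), tags per kb, exonic peaks only, exon length as a covariate, control windows within 1 exon, motifs by region, position on the mRNA, the tests of region shares between the libraries and against an even spread, overlap by region and by tags, and the comparison of the alternative with the classical activation list.

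The tests were tried on simulated data. With 30.0% of 15511 placed peaks copied to a second list, the placement test recovered 28.0% above placement, and with none copied the ratio of observed to placed was 0.940. In 100 simulations of the list test, 1 made any call with no list raised, and a list raised to 50% of members was called in 88.0% of them. In 50 simulations of the motif test, all passed with GGAC written into a part of the sequences, and 2.0% passed with none added. Simulated peaks lay evenly along gene spans, as the placement test assumes. Genes outside the raised list had equal chances of a peak, and sequences had equal base shares. The simulations therefore do not test biases from exon position, expression, length or base composition.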

Results

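IGF2BP2 is an RNA-binding protein described as a reader of m6A, a methyl mark on adenosines of mRNA. The series asks which RNAs it binds in mouse macrophages, and its title names TSC1 and PPARγ. The 2 peak lists were compared, 1 for each immunoprecipitation library. Replicate 1 held 15511 peaks with 189393 tags, in 4950 genes. Replicate 2 held 22570 peaks with 324456 tags, in 6052 genes. The median peak had 7 and 8 tags and a length of 195 and 215 nt. The values below are per library, with n = 2 immunoprecipitation libraries and no input values.

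Tsc1, which encodes hamartin, an inhibitor of mTORC1 signalling, had 1 peak in replicate 1 and 3 in replicate 2. One position was found in both, on chromosome 2 (GRCm38) at 28686824 to 28687023 with 6 tags in replicate 1 and at 28686753 to 28687055 with 13 tags in replicate 2. It lay in exon 23 of 23, in the coding sequence of the principal transcript, 147 and 115 nt before its end. By the reference annotation over all transcripts, which ranks 3' UTR first, both peaks were in 3' UTR. The 2 peaks held 4 and 8 DRACH motifs and 1 and 2 GGAC motifs. The other replicate 2 peaks of Tsc1 did not lie wholly within 1 exon of that transcript. That at 28678099 to 28678280, with 8 tags, was at exon 16 and was intronic by the authors' annotation. That at 28685984 to 28686146, with 10 tags, was at exon 22 and was coding sequence by the authors' annotation. The shared Tsc1 peaks were not among the strong ones: 32.5% and 69.9% of the peaks in their libraries had fewer tags.

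Pparg, which encodes a lipid-sensing nuclear receptor, had 3 peaks in replicate 1, all in introns. It had 10 in replicate 2, of which 1 lay in the 5' UTR and the others in introns. A single Pparg position, on chromosome 6, was shared by the rule of at least 1 bp of overlap. It ran from 115400029 to 115400526 with 13 tags in replicate 1 and from 115400349 to 115400750 with 11 tags in replicate 2. These peaks overlapped only in part. The replicate 1 summit, at 115400171, lay outside the replicate 2 peak, and the replicate 2 summit, at 115400452, lay within the replicate 1 peak. The strongest Pparg peak, at 115385196 to 115385834 with 22 tags, was in replicate 2 and had no partner in replicate 1. Igf2bp2 itself had no sense peak in the replicate 1 list and 3 in replicate 2, of which the strongest had 9 tags. These are tag counts of single libraries with no input value, so none of them is an enrichment.

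**Figure D1:**
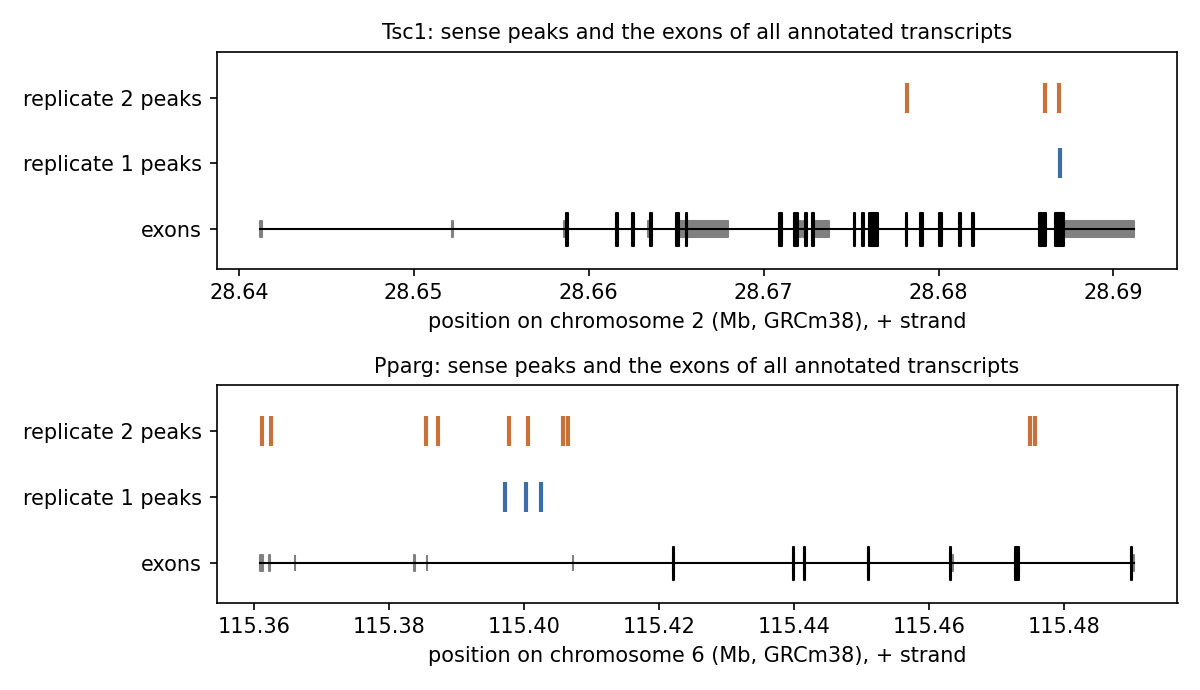
Sense peaks of Tsc1 (top) and Pparg (bottom) along their chromosomes in Mb, with 1 mark at the middle of each peak for replicate 1 and replicate 2, above the exons of all annotated transcripts (black, coding; grey, non-coding). The shared Tsc1 position lies in the last exon, and the shared Pparg position at 115400029 to 115400526 lies in an intron. The Pparg peaks there overlap only in part, and the replicate 1 summit lies outside the replicate 2 peak.

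The 20 genes with the strongest peaks, among genes with a shared peak, are given in the order of their mean rank over the libraries. The tags given are those of the strongest peak of each library, which was not always at the same place in both. The peak named for mt-Nd1 came first with 11155 and 13688 tags and had its summit in the mitochondrial rRNA gene mt-Rnr2. The peak named for AY036118 had 4702 and 5256 tags, with its summit in the rRNA gene CT010467.1. Gm10800 followed with 809 and 1067 tags, then Psap (445 and 606), Atp6v0a1 (409 and 542) and Gpnmb (267 and 1153), of which the last 2 tied. Whether repeats or uneven read mapping gave the Gm10800 peak was not tested. Next were Ctsd, which encodes the lysosomal protease cathepsin D (269 and 370 tags), Ahnak (225 and 361) and the receptor gene Csf1r (215 and 363). Grn (169 and 431) and Plec (154 and 578) tied before Sirpa (200 and 302), the filamin gene Flna (176 and 331) and the cathepsin gene Ctsb (139 and 315). Fam20c (125 and 349), Mfsd12 (177 and 187), the actin gene Actb (156 and 191) and Lgals3 (181 and 178) came before the ferritin gene Fth1 (214 and 163) and the lipase gene Lpl (114 and 252), which tied. Of these genes, Psap, Ctsd, Grn and Ctsb were members of the lysosome list, and Gpnmb, Ctsd, Csf1r, Ctsb and Lgals3 of the macrophage identity list. Flna and Actb were members of the actin list. By the authors' regions, the strongest peaks of Psap, Ctsd, Csf1r, Grn, Ctsb and Lgals3 lay in introns in both libraries. Those of Gm10800, Ahnak, Plec, Flna and Actb lay in coding sequence in both. The reference annotation at the peak midpoint differed for some of them. It gave intron for Flna and Plec in replicate 1 and 3' UTR for Flna in replicate 2. It gave coding sequence for Ctsb in replicate 1 and Grn in replicate 2. The strongest peaks of Atp6v0a1, Gpnmb, Plec, Sirpa, Ctsb, Fam20c, Mfsd12, Lgals3, Fth1 and Lpl lay at different places in the 2 libraries, and those of the other genes overlapped.

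Peaks recurred at the same places far more often than random placement in their genes gave. Of the replicate 1 peaks, 34.8% (95% interval 34.1 to 35.6) were overlapped in replicate 2, against 5.98% after placement, a 5.82-fold excess. Of the replicate 2 peaks, 23.6% (23.1 to 24.2) were overlapped in replicate 1, against 4.04%, a 5.84-fold excess. Both p-values were 0.000999, the smallest that 1000 placements can give. The share was 46.3% and 31.4% for coding-sequence peaks, 24.1% and 17.2% for intronic peaks, and 18.6% and 12.7% for antisense peaks. It rose with tags, from 11.1% of peaks with 3 to 5 tags to 76.3% of those with 50 or more in replicate 1, and from 5.54% to 74.9% in replicate 2. When peaks were placed within the same region of the same gene, a choice made after seeing the data, the excess was 2.04-fold and 2.10-fold, above each of 200 placements. Antisense peaks were still placed along the gene span there (4.07-fold and 4.12-fold). Intergenic peaks, where no gene was named, were placed on the chromosome (37.2-fold and 33.9-fold). Both raise the pooled excess. With placement in the same region, coding-sequence peaks were 1.67-fold and 1.69-fold above placement, 3' UTR peaks 1.37-fold and 1.38-fold, and intronic peaks 4.75-fold and 4.82-fold. With placement anywhere in the gene and overlap of at least 50% of both peaks, the excess over all peaks was 14.9-fold and 14.8-fold.

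**Figure D2:**
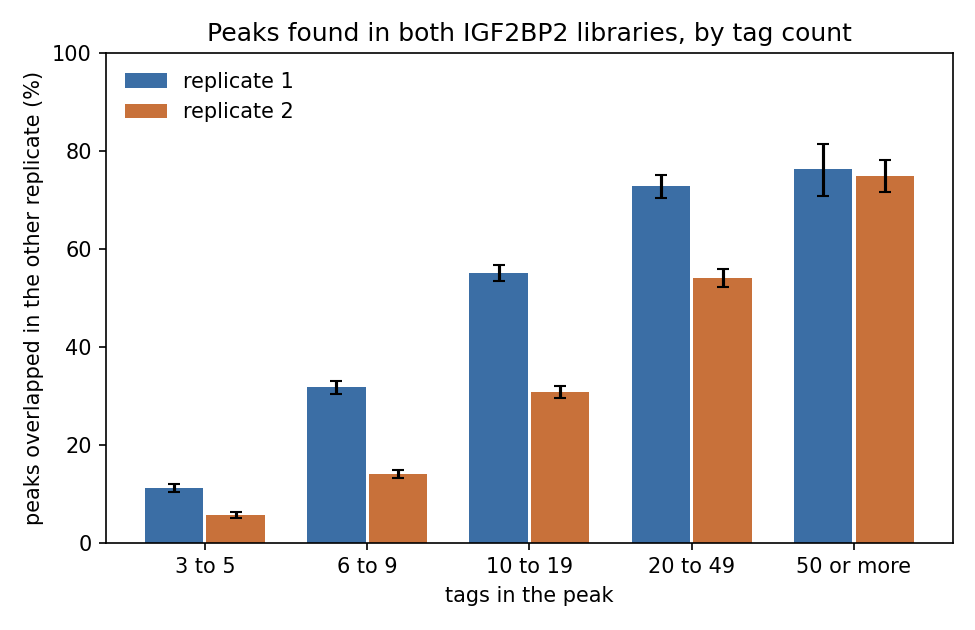
Percent of peaks overlapped by at least 1 bp on the same strand in the other library (vertical axis) by tags in the peak (horizontal axis), with exact 95% binomial intervals as bars. The share rises from 11.1% to 76.3% in replicate 1 and from 5.54% to 74.9% in replicate 2.

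At the level of genes, 3808 had a peak in both lists, which was 76.9% of the genes of replicate 1 and 62.9% of those of replicate 2. Chance among all annotated genes gave 539.4, a 7.06-fold excess (one-sided Fisher's exact test, log10 p = -3158). With the stronger 50% of each list it was 15.5-fold. Among protein-coding genes alone the excess was 2.91-fold, with 3739 shared. Which genes macrophages express was not measured in these files, so the excess does not separate binding from expression. Over the 5404 overlapping pairs, tag counts correlated across peaks, with a Spearman's rho of 0.763 and a Pearson's r of 0.796 on log2 tags. This describes peaks within 1 pair of libraries.

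Coding sequence and introns held most peaks. Coding sequence held 40.8% (40.0 to 41.6) of replicate 1 peaks and 38.4% (37.7 to 39.0) of replicate 2 peaks, and introns 32.9% (32.2 to 33.7) and 35.4% (34.8 to 36.0). The 3' UTR held 10.8% and 10.1%, the 5' UTR 2.34% and 2.31%, non-coding exons 0.426% and 0.505%, antisense positions 4.26% and 4.32%, and intergenic positions 8.47% and 8.98%. Replicate 2 had a smaller share of its peaks in coding sequence (adjusted p = 9.24e-06) and a larger share in introns (adjusted p = 5.45e-06) by Fisher's exact test, and the other regions did not pass it. Relative to their length within the same gene spans, by the reference annotation, coding sequence held 7.61 and 7.44 times the peaks of an even spread. The 3' UTR held 3.09 times in each library, the 5' UTR 2.60 and 2.69 times, and introns 0.398 and 0.422 times. These spans include introns, which spliced mRNA lacks, so the folds do not show a preference within the mRNA or for binding. The 3' UTR share was 17.3% and 16.7%, over 1.5 times as high, when the reference annotation at the peak midpoint replaced the authors' region covering most of the peak. The reference class also ranked 3' UTR first over all transcripts, which favours the 3' UTR. How much each of these changes moved the share was not tested.

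Peaks lying within 1 exon were few near the 3' ends of mRNAs. Only 2.50% of 3205 such peaks in replicate 1 and 2.68% of 3994 in replicate 2 had their midpoint in the last 200 nt, 0.433 and 0.492 times the even expectation. With no input value, low numbers near mRNA ends cannot be told apart from low read coverage there. Near the stop codon, within 200 nt, peaks were 1.12 and 1.10 times the expectation, near the start codon 1.60 and 1.70 times, and in coding sequence 1.73 and 1.75 times. In the 5' UTR they were 0.907 and 0.944 times the expectation. These comparisons were chosen after seeing the data and the expectation covers only positions where the peak fits in 1 exon. With the whole mRNA as expectation the fold near the stop codon was 1.34 and 1.31, that near the start codon 0.963 and 0.964, that in coding sequence 1.03 and 1.01, and that near the 3' end 0.434 and 0.474. The 5' UTR fold was then 0.695 and 0.69. The 3' UTR went from 0.670 and 0.682 to 1.01 and 1.03 with that change, so no direction is given for it or for the start codon.

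Of the m6A motifs, GGAC was more frequent in peaks than in control windows, by a small margin, and DRACH had no set direction. DRACH was present in 93.2% of replicate 1 peaks and 94.0% of replicate 2 peaks, against 93.2% and 93.4% of controls (odds ratio 1.0 and 1.11, Fisher's exact p = 1 and 0.269), close to the ceiling of this measure. In replicate 2 fewer peaks than shuffled sequences held DRACH (odds ratio 0.815, exact p = 0.0433, range over 10 draws 0.806 to 0.934), and more peaks than control windows did when both were extended by 50 nt (99.4% against 98.9%, odds ratio 1.73, exact p = 0.0376, the highest of 10 draws, whose lowest was 1.12). GGAC was present in 58.2% against 54.0% in replicate 1 (odds ratio 1.19, Fisher's exact p = 0.000678, range over 10 draws 1.16 to 1.25). In replicate 2 it was present in 58.6% against 55.1% (odds ratio 1.15, Fisher's exact p = 0.00182), the highest odds ratio of 10 draws, whose lowest was 1.04. Against shuffled peak sequences the odds ratio of GGAC was 1.11 in replicate 1 (exact p = 0.0410, range over 10 draws 1.05 to 1.16) and 0.970 in replicate 2 (exact p = 0.524, range 0.965 to 1.05), where the call ended. Against control windows within 1 exon, the draw tested gave 1.21 in replicate 1 (exact p = 0.000239), the highest of 10 draws, whose lowest was 1.10. In replicate 2 it gave 1.04 (exact p = 0.401), the lowest of 10 draws, whose highest was 1.13, so these windows do not settle whether the replicates differ, and the difference was not tested. Counted per kb, which was not tested, GGAC occurred 4.68 times in replicate 1 peaks, against 4.14 ± 0.0695 in control windows (SD over 10 draws), 4.29 ± 0.0688 in shuffled sequences and 4.24 ± 0.0698 in windows within 1 exon. In replicate 2 it occurred 4.45 times per kb, against 4.00 ± 0.0716, 4.18 ± 0.0600 and 4.11 ± 0.0577, so its density stayed above that of each control in both libraries. TGGAC, tried after seeing the data, was present in 25.9% against 24.2% and in 26.4% against 25.4% (Fisher's exact p = 0.134 and 0.358). In replicate 1 it passed against windows within 1 exon (1.18, exact p = 0.00434) and in the stronger 50% of peaks (1.17, exact p = 0.0410), each the highest of 10 draws, whose lowest were 1.12 and 1.03. It also passed in replicate 1 in 3' UTR peaks (1.29, exact p = 0.00422, range over draws 1.07 to 1.32), and in replicate 2 in no setting run. These p-values of 3 motifs over several settings were not adjusted.

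Lysosomal genes were the list most often found in both libraries, with 26 of 28 members (odds ratio 64.0, exact adjusted p = 4.18e-17), led by Psap, Ctsd, Grn and Ctsb. Actin cytoskeleton and adhesion genes followed with 25 of 28 (odds ratio 41.0, exact adjusted p = 9.00e-16), among them Flna, Actb, Tln1 and Vim. Glycolysis genes had 14 of 19 (odds ratio 13.7, exact adjusted p = 3.58e-07), such as Hk3, Pkm, Ldha and Aldoa, while Gapdh, named after its values were seen, had no sense peak in either list. No peak of Pkm overlapped between the libraries. Macrophage identity genes had 20 of 28 (odds ratio 12.3, exact adjusted p = 1.74e-09), among them Gpnmb, Ctsd and Csf1r. Across all protein-coding genes 17.0% of 22028 had a peak in both libraries, and these tests were two-sided Fisher's exact tests. These 4 lists also passed against the 6950 protein-coding genes with a peak in either library, with odds ratios of 11.2 for lysosomal, 21.6 for actin, 6.03 for glycolysis and 3.45 for macrophage identity genes. Across the settings run, the highest finite odds ratios were 86.3, 49.9, 18.3 and 25.3. In 1 library alone the actin list had 23.1 in replicate 2 and the macrophage identity list 21.5 in replicate 1, over 1.5 times from the values above, and all 28 lysosomal genes had a peak in replicate 2. No expression value was used, so the counts do not separate binding from abundance.

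Genes of PPARG signalling and alternative activation, the macrophage state driven by interleukin 4, had 18 of 30 members in both libraries (odds ratio 7.37, exact adjusted p = 5.10e-07). They included Lpl (203 and 916 tags in all), the mannose receptor gene Mrc1 (1030 and 1880), Arg1 (122 and 199) and the cholesterol exporter gene Abcg1 (311 and 520), and Pparg itself. TSC and mTORC1 pathway genes had 18 of 40 (odds ratio 4.02, exact adjusted p = 9.91e-05), among them Tsc1, Tsc2 (named after its values were seen), Rptor (68 and 74 tags), Tfeb (35 and 67), Akt1 (43 and 47) and Pik3cd (39 and 82). No peak of Tfeb or Pik3cd overlapped between the libraries. The m6A machinery had 10 of 24 (odds ratio 3.50, exact adjusted p = 0.00858), with Hnrnpa2b1 (193 and 188 tags), Prrc2a (195 and 356), Ythdf3 (34 and 56) and Hnrnpc (55 and 15). Against the genes with a peak in either library these calls ended: the odds ratio was 3.10 for the PPARG list, 1.55 for the TSC list and 1.07 for the m6A machinery. The TSC list had an odds ratio of 6.65 in replicate 1 alone (26 of 40) and 2.76 in replicate 2 alone (20 of 40), called in both. The PPARG list had 14.8 with the stronger 50% of each list and 11.3 with exon length as a covariate. The m6A machinery also lost its call with exonic peaks only (2.55) and with exon length as a covariate (1.73).

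Classical activation genes, those of the inflammatory state, had 9 of 32 members in both libraries (odds ratio 1.92, exact adjusted p = 0.163), led by Marcks (97 and 110 tags), Nfkb1 (104 and 142), Irf5 (36 and 115) and Ccl2 (17 and 34). Tnf, Il1b, Il6 and Nos2, named after their values were seen, had no sense peak in either list. Set against it directly, the alternative list was more often found (18 of 30 against 9 of 32, odds ratio 3.83, two-sided Fisher's exact p = 0.0204), a comparison chosen after seeing the data and not controlled for expression. With the stronger 50% of each list it was 17 of 30 against 5 of 32 (odds ratio 7.06). The classical list passed the test in replicate 1 alone (odds ratio 2.44) and with gene length or exon length as a covariate (2.83 and 2.76). Against genes with a peak in either library its direction turned (0.858).

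Reported targets of the IGF2BP family, a list drawn up from general knowledge, had 6 of 17 members in both libraries (odds ratio 2.67, exact adjusted p = 0.0979), including Actb, Cd44 (208 and 542 tags), Ccnd1 (23 and 47) and Hmga1 (34 and 39). No peak of Ccnd1 overlapped between the libraries. The list of reported targets passed in replicate 1 alone (odds ratio 3.17) and with the stronger 50% of each list (4.69). Ribosomal protein genes had 23 of 83 (odds ratio 1.88, exact adjusted p = 0.0250), with Rps3, Rps9, Rpsa and Rpl3 ranked highest, and lost the call with exonic peaks only (1.17) and against genes with a peak in either library (0.789). The strongest Rps3 peak had 18 tags in replicate 1 and 94 in replicate 2, where its summit also lay in the snoRNA gene Snord15b. By the authors' regions all Rpl3 peaks were intronic. With gene length or exon length as a covariate the ribosomal protein list kept its call, with odds ratios of 5.43 and 5.11. Histone genes had 2 of 82, H3f3b and H2afy (odds ratio 0.122, exact adjusted p = 0.000210). The histone call ended with gene length (0.537) or exon length (0.588) as a covariate, with the stronger 50% of each list (0.280) and against genes with a peak in either library (0.343). Of the 13 protein-coding genes of the mitochondrial genome, mt-Nd1 and mt-Nd4 were in both libraries (odds ratio 0.889, exact adjusted p = 1), and the mt-Nd1 peak had its summit in mt-Rnr2. With gene length or exon length as a covariate this list turned in direction and passed the test (5.91 and 6.95).

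Markers of other cell types were rarely in both libraries. Neutrophil markers had 1 of 12 (Csf3r; exact adjusted p = 0.792), dendritic cell markers 1 of 9 (Batf3; exact adjusted p = 1) and fibroblast markers 1 of 11 (Fn1; exact adjusted p = 0.792). T cell markers had 0 of 9 (exact adjusted p = 0.516), B cell markers 0 of 7 (exact adjusted p = 0.785) and erythroid markers 0 of 9 (exact adjusted p = 0.516). None of these 6 lists differed from other protein-coding genes in Fisher's exact test, and lists of this size leave wide intervals.

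**Figure D3:**
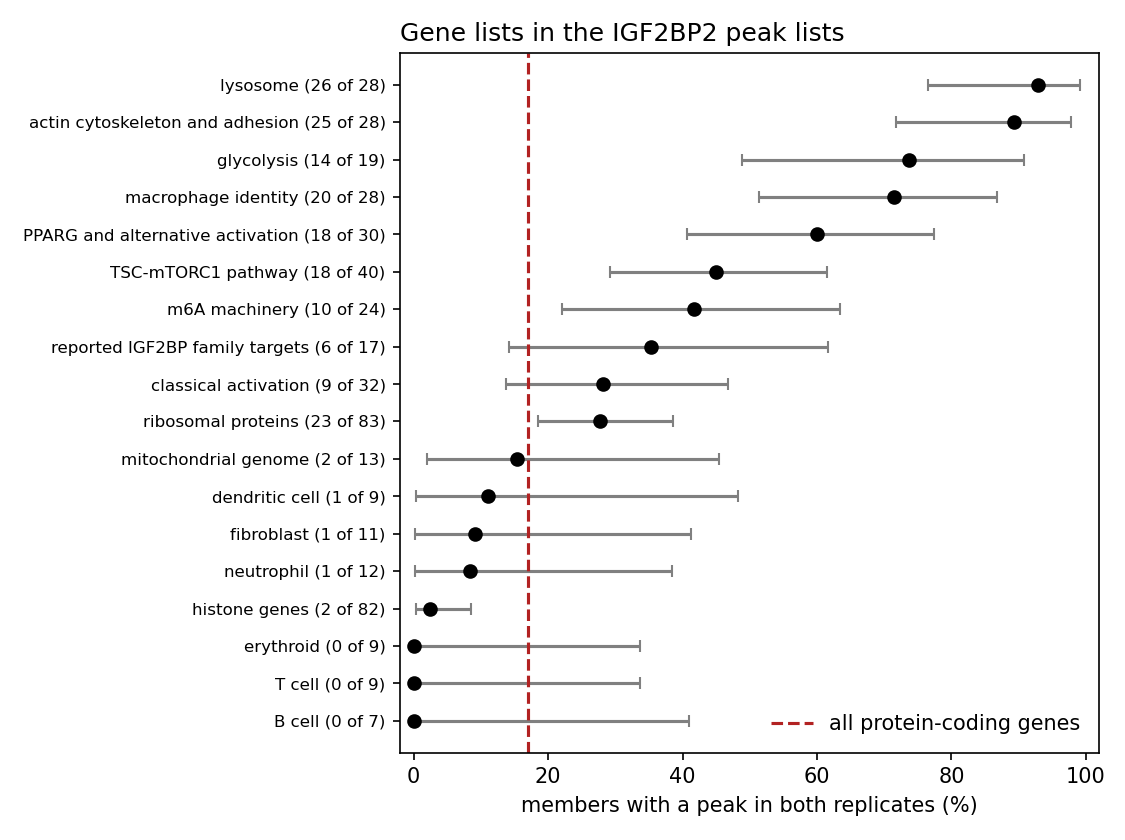
Percent of the members of each gene list with a peak in both libraries (points, with exact 95% binomial intervals as bars), with the count of members beside each name. The dashed line is the 17.0% of all protein-coding genes. Lysosomal (26 of 28) and actin (25 of 28) genes lie highest, and histone genes (2 of 82) lie below the line.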

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

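The test of annotated genes opposite the antisense peaks was chosen after the result was seen; the test of sense peaks opposite them was written before. The rRNA loci were also chosen after the values were seen.

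These results stand here because they are signal outside the sense mRNA peaks that the series is about, above the limit that a count of 0 allows. The mt-Rnr2 peaks, the mt-Rnr1 peak and the strongest peaks of the chromosome 17 locus did enter the gene comparisons, under the authors' gene names mt-Nd1, mt-Tv and AY036118. Part of this signal lay in peaks over ribosomal RNA genes. A peak with its summit in the mitochondrial rRNA gene mt-Rnr2 ran from 1087 to 3693 in replicate 1 and from 1087 to 3702 in replicate 2. It also covered most of mt-Nd1 (2751 to 3707), so its tags cannot all be given to the rRNA. The peak held 11155 tags in replicate 1, 5.89% of the tags in that library's peaks (exact 95% interval 5.78 to 6.00). In replicate 2 it held 13688, 4.22% (4.15 to 4.29). A peak over mt-Rnr1, at positions 79 to 1049 of the mitochondrial genome, held 6700 tags in replicate 1, 3.54% of the total. No mt-Rnr1 peak was in the replicate 2 list used here. On chromosome 17, the locus of AY036118 and the rRNA gene CT010467.1 held 5191 tags in 9 peaks of replicate 1 (2.74%) and 5720 in 10 peaks of replicate 2 (1.76%).

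Antisense peaks, which have no gene in the comparisons, numbered 661 in replicate 1 and 975 in replicate 2. Sense RNA read on the wrong strand would place most of them opposite a sense peak. In fact 9.99% (exact 95% interval 7.81 to 12.5) and 11.6% (9.65 to 13.8) lay opposite one, against 2.38% and 3.85% after placement in the gene (p = 0.000999 in both, the smallest possible). This argues against strand errors as the cause of most antisense peaks and leaves them open for the part opposite sense peaks, where the median ratio of antisense to sense tags was 0.189 and 0.185. Reference genes that the authors' annotation lacked would account for few: 5.75% and 7.90% overlapped a reference gene on their own strand. Genes absent from the reference annotation as well could not be tested this way, so they stay open. Antisense peaks recurred 4.07-fold and 4.10-fold above placement, and no biological explanation was tested.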

How the results depend on the processing

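Of 203 alternatives to 41 results, 147 kept the direction and the side of the threshold, or stayed within the spread of the replicates. With 2 libraries, a region share from either library alone lies within that spread by arithmetic, so those settings test nothing. Results that were uncalled and stayed uncalled are also among the 147. No paired analysis was possible because the files used here hold peaks of the immunoprecipitates alone, with no input value to pair with them. Tests chosen after seeing the data were those with exonic peaks only, exon length, control windows within 1 exon, motifs by region, same-region placement, tags per kb, TGGAC, region shares between libraries and against an even spread, overlap by region and by tags, the alternative against the classical list, and position on the mRNA. Where a value changed, the cause was not tested. Unknown library depth limits all comparisons between libraries. For all peaks together, overlap exceeded placement in every setting run (2.04-fold to 14.9-fold). The alternative list exceeded the classical one in each of its settings (odds ratio 2.92 to 7.06).

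With the stronger 50% of each list, coding-sequence peaks made up 46.3%, 3' UTR peaks 12.3%, antisense peaks 0.975% and intergenic peaks 2.92%, and 1825 genes were shared. In shared peaks only, coding sequence made up 52.6%, introns 24.3%, 3' UTR 12.6%, 5' UTR 2.73%, antisense 2.30% and intergenic 5.11%. By the reference annotation at the peak midpoint, which changes both the annotation and the rule and ranks 3' UTR first, these were 35.0%, 31.2%, 17.0%, 2.99%, 4.22% and 6.40%. Spearman's rho was 0.781 with maximum height and 0.821 with overlap of at least 50%.

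Odds ratios against genes with a peak in either replicate were 1.55 for the TSC list, 3.10 for PPARG, 1.07 for m6A machinery and 0.343 for histone genes, all no longer called, and 0.858 for classical activation and 0.789 for ribosomal proteins, both in the other direction. With the stronger 50%, reported IGF2BP targets became called (4.69) and histone genes lost their call (0.280). Neutrophil (1.02) and fibroblast (1.12) markers then changed direction, uncalled. Without 1 replicate, classical activation ranged from 2.15 to 2.44, reported targets from 2.45 to 3.17, and the mitochondrial genome from 1.07 to 1.23. The last was 2.04 with the stronger 50%, 1.39 with exonic peaks only, 5.91 with gene length and 6.95 with exon length, called in the last 2 settings, against 0.889. With exonic peaks only, m6A machinery (2.55) and ribosomal proteins (1.17) lost their calls. Classical activation became called with gene length (2.83) and exon length (2.76). Histone genes lost theirs with both (0.537 and 0.588), and m6A machinery with exon length (1.73). Neutrophil markers reached 1.35 with exon length, uncalled. An odds ratio could not be had where every member or no member had a peak: lysosomal genes without replicate 1, and dendritic and erythroid markers against genes with a peak, with T cell, B cell and erythroid markers under both length covariates.

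In replicate 2, DRACH became called in extended peaks (odds ratio 1.73, the highest of 10 draws, whose lowest was 1.12) and as a deficit against shuffled sequences (0.815, with draws from 0.806 to 0.934). It was 0.809 in coding-sequence peaks, uncalled and the lowest of 10 draws, whose highest was 1.06, so its direction is not set. GGAC in replicate 2 lost its call against shuffled sequences (0.970), against windows within 1 exon (1.04, the lowest of 10 draws), in 5' UTR peaks (1.46) and in coding-sequence peaks (1.02), while GGAC per kb stayed above shuffled sequences (4.45 against 4.18), windows within 1 exon (4.11) and, in coding-sequence peaks, control windows (5.41 against 4.96). In replicate 1 it lost it in 5' UTR peaks (1.57). On the whole mRNA, the 3' UTR fold changed direction to 1.01 in replicate 1 and 1.03 in replicate 2, and the coding-sequence fold in replicate 2 was 1.01, no longer called.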

Other observations

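The tests of even pre-mRNA spread, of summits in reference exons and of short mRNAs were chosen after the results were seen; those of shared sequence and of snoRNAs were written before.

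Intronic peaks made up 32.9% and 35.4% of the lists. Evenly spread pre-mRNA would put them at chance positions, yet they recurred 4.75-fold and 4.82-fold above placement in introns of the same gene. This argues against an even spread as the whole cause for the class. The count includes peaks with their summit in an exon (1056 of 5108 and 1916 of 7985), which could recur whatever the spread of pre-mRNA. Recurrence was not computed without them, so an even spread stays open for peaks with their summit in an intron. Reference exons that the authors' annotation lacked, or peaks drawn across an intron, would put the summits in reference exons. They did so for 20.7% (exact 95% interval 19.6 to 21.8) and 24.0% (23.06 to 24.95) of intronic peaks, which argues against this for most of them. The share was 7.67% and 8.34% of wholly intronic peaks. Of intronic peaks that also held exon it was 70.05% and 73.5%, so for those this explanation stays open. Among intronic peaks of 50 or more tags the share was 52.4% and 45.5%, so for strong peaks it stays open, as do repeats and uneven read mapping, which were not tested.

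Ribosomal protein genes, though 23 of 83 had a peak in both libraries, had an exonic peak in both for 11 (13.3%), against 3.70% of other genes of similar mRNA length, so no deficit was seen against those genes. Ribosomal protein genes with an exonic peak in either library had more sequence of their own: 64.2% ± 23.3 (SD, n = 23) of their 50-mers occurred in no other gene's transcripts, against 44.1% ± 27.0 (SD, n = 60), a difference of 20.2 percentage points (two-sided permutation p = 0.00236). Reads shared with pseudogenes and paralogs may therefore bear on which of these genes had an exonic peak, as a hypothesis; mRNAs with an exonic peak were also longer, at a median of 1020 against 834 nt. Whether short mRNAs matter cannot be told apart: the difference from genes of similar length was 9.56 points, and the low share of those genes left no room for a clear deficit. Of their intronic peaks, 45.0% (9 of 20) and 43.8% (14 of 32) overlapped a snoRNA gene, against 4.94% and 7.51% after placement and above every placement, but the exact intervals (23.1 to 68.5 and 26.4 to 62.3) span 50%, so whether snoRNAs account for most cannot be told apart with so few peaks.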
